A study of Mus musculus with 9 samples.

How the data were processed

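The data are RNA sequencing of mouse aortic arch, 9 libraries in 3 groups of 3. Per the labels' protocols, RNA was extracted with TRIzol from tissue ground in liquid nitrogen, 1.5 micrograms went into each library, messenger RNA was purified, and libraries were made with an NEBNext Ultra kit. The series describes 120 mice in groups of 20, and all 9 libraries carry batch label 1. Groups were taken from the sample titles, and columns of the table were matched to titles by name. Columns AS were taken as model, since only that group is described as AS, columns HD as high dose and the misspelt Contorl as control, each with the replicate number of the title.

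The authors deposited 1 table of FPKM values, which are fragments scaled by gene length and by the fragments of the library. It holds 21989 genes, all marked protein-coding. The genome builds GRCm38.p5 and mm10 come from the submitters' processing notes. The aligner, the counting tool and the strand setting are not given in the sources used here. FPKM is relative to each library's total, so genes that take a large share lower all others, and the table holds no counts, so no count model was used. Of the gene names, 27 are date-like, as spreadsheet software makes them, and 2 of these occur more than once. Gene positions came from GENCODE release M21 on GRCm38, in which 20641 of the 21989 names (93.9%) were found.

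Depth was estimated from the steps between FPKM values under 0.2, which follow whole fragments. Relative depth was additive between libraries to within 0.006 on the log2 scale, and lay between 56.3% in control 2 and 100% in model 1, a ratio of 1.78. Absolute depth, from annotated exon lengths of 5752 genes of which 15.7% lay within 0.05 log2 of the peak, was too approximate to be used. No counting interval was computed.

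Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 9 libraries in 1 fit, a mean per group, empirical Bayes with a trend and Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. Genes needed at least 1 FPKM in at least 3 libraries, which 12895 did. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Values are FPKM means ± SD of 3 libraries, and log2 differences carry the standard error of the fit. Gene lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists with at least 5 tested members. No list passed with an estimated correlation in any of the 3 comparisons, where the smallest adjusted p was 0.278, 0.745 and 0.223. The 30 lists held 515 entries, of which 511 were in the table and 467 were tested. The tests, the lists and all but 2 of the alternatives were chosen before the data were examined. Figures were drawn with matplotlib 3.10.9 from Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

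Named genes followed a rule fixed before the data were examined. They were Apoe; in each comparison the 5 genes of smallest p in each direction among those without overlap between groups and with a mean of at least 2 FPKM in the higher group, since none passed, leaving out names of clones and predicted genes; the 1 or 2 members of smallest p in each list that passed; and 14 genes fixed for every comparison, of which those given are Cd68, Trem2, Acta2, Myh11, Abca1, Cpt1a, Hmox1, Nqo1, Sod2, Cybb, Ccl2 and Vcam1. Of the genes this rule selects, 3 are not reported here and are left out of the counts of named genes, while the list tests keep them. Genes of neighbouring tissues given per library, and the genes named under an alternative setting, were chosen after their values were seen. Reads of Hba-a1 and Hba-a2, of Hbb-bs and Hbb-bt and of Acot1 and Acot2 can be split arbitrarily between near-identical copies.

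The procedure was tested on simulated data for model against control with the real means and spread of 12895 genes. Of 200 genes changed by a log2 of 1, 2 and 4, limma recovered 0%, 68.5% and 94%, and it called 0 genes where none was changed. The changed genes were drawn from those of higher expression, and 8 to 12 unchanged genes were called in the runs that recovered any. With a spread factor of 0.25 it recovered 89.5%, 98.5% and 100%. Camera called 0 of 29 random lists. Genes were simulated independently of each other, so this could not test the preset correlation of 0.01. Estimated correlations of the real lists ran from -0.0105 for the antioxidant list to 0.906 for the cardiac list. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, robust empirical Bayes, array weights, only the 2 groups compared, the replicate number as a block, a log2 threshold of 1, each library left out, and an estimated correlation for lists. Added after seeing the data were the cardiac list mean as a covariate and the use of only the 5 libraries low in cardiac genes. The overlap of list means between libraries was counted after seeing the data. The alternatives planned for counts were not run, since the table holds none.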

Results

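RNA sequencing measured gene expression in the mouse aortic arch, the curved part of the aorta and an early site of atherosclerotic plaque. The 9 libraries formed 3 groups of 3. Control libraries came from C57BL/6J mice on a standard diet. Model libraries came from mice without ApoE, an apolipoprotein that clears remnant lipoproteins from the blood, after 15 weeks on a high-fat diet. High dose libraries came from mice of the same genotype and diet that received 5.12 g/kg/day of the preparation named ZCL in the labels, by gavage for 15 weeks. The series concerns the plant Ziziphora clinopodioides Lam., lipid metabolism and oxidative stress. Genotype and diet differed together between control and model. An atorvastatin group and the groups on 1.28 and 2.56 g/kg/day of ZCL were not analysed here. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

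Expression was deposited as FPKM, with 21989 protein-coding genes per library. The steps between low FPKM values put the depth of control 2, the lowest, at 56.3% of that of model 1, the highest. Genes at 1 FPKM or more numbered between 11314 in control 3 and 13191 in control 2. Haemoglobin genes took 14.3% of summed FPKM in model 1, 8.71% in model 2 and 4.95% in model 3, against 1.99% to 3.69% in control, and in high dose 0.666%, 0.567% and 4.59%. Of the 21989 genes, 12895 reached 1 FPKM in at least 3 libraries and were tested.

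Genes of neighbouring tissues differed strongly between libraries of the same group. Myh6, the alpha heavy chain of heart muscle myosin, stood at 2729 FPKM in control 1, 807 in control 2, 634 in high dose 2 and 1554 in high dose 3, and between 1.85 and 6.34 in the other 5 libraries. The atrial peptide gene Nppa followed the same division, with 6483 FPKM in control 1 and 9.35 in model 1. The airway secretory gene Scgb1a1 reached 20438 FPKM in high dose 2 and 6425 in control 2, and no other library passed 68.6. Catecholamine synthesis genes were concentrated in high dose 1, where Th stood at 599.8 and Dbh at 839 FPKM. Acta1, the skeletal muscle actin, reached 3707 FPKM in high dose 2. Ucp1, the uncoupling protein of brown fat, reached 7979 FPKM in control 3. Across genes, the 3 model libraries correlated at 0.923 to 0.978 with each other, while the control libraries correlated at 0.856 to 0.916 and the high dose libraries at 0.789 to 0.872; genes are not independent replicates.

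**Figure D1:**
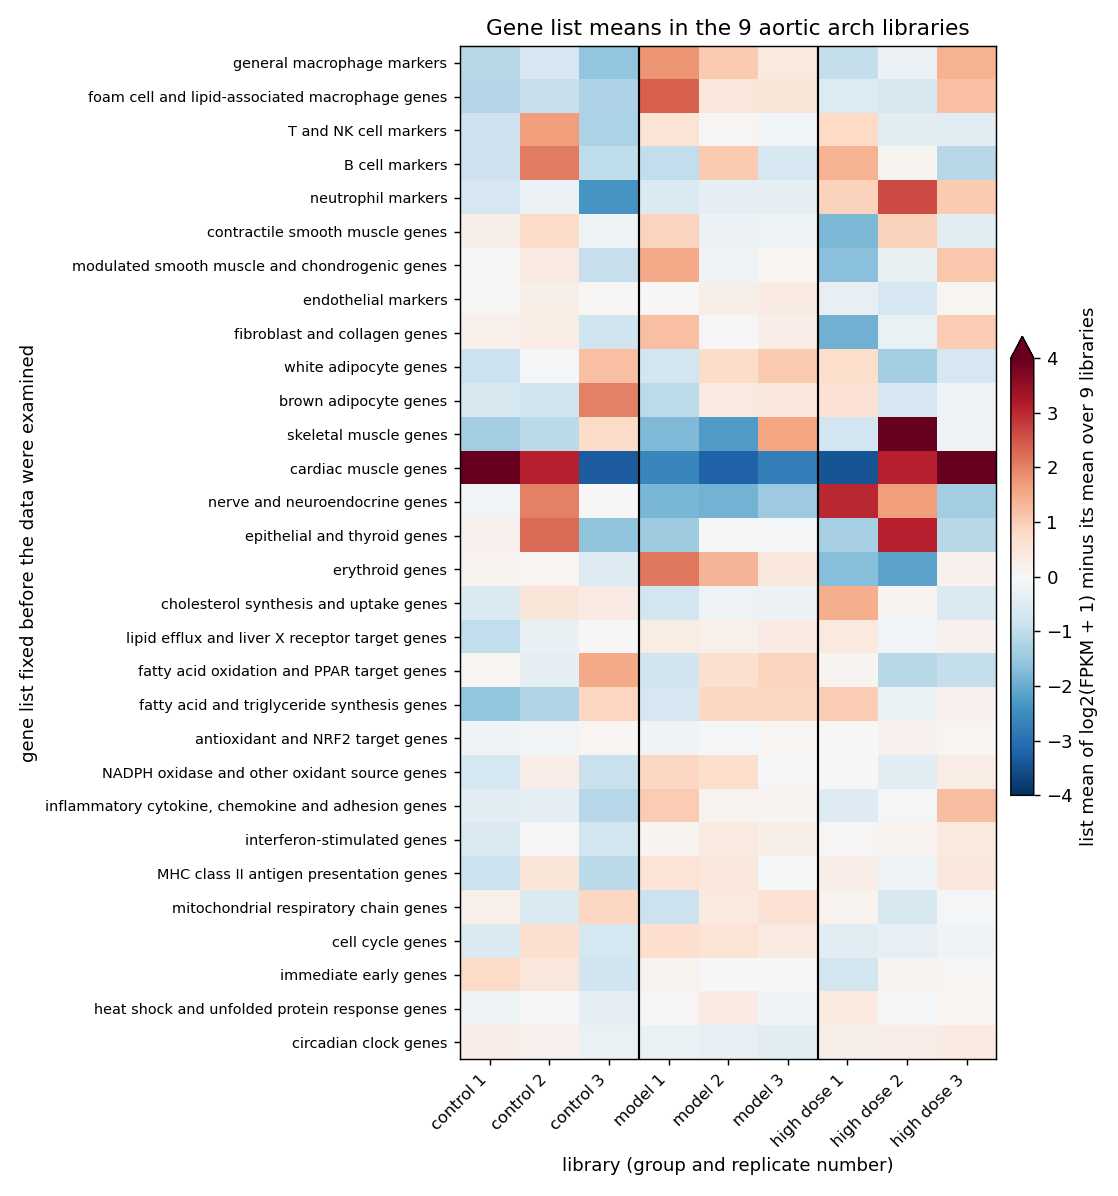
Mean log2(FPKM + 1) of each of 30 gene lists (rows) in each of the 9 libraries (columns), minus the list's mean over the 9 libraries, on a colour scale from -4 to 4. The cardiac list stands at 9.78, 8.25, 8.24 and 9.66 in control 1, control 2, high dose 2 and high dose 3 before subtraction, and at 1.68 to 2.52 in the other 5.

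Apoe was read first as a check of the labels. On chromosome 7, 19696109 to 19699188 in GRCm38, it stood at 829, 1006 and 339.9 FPKM in control 1, 2 and 3, and at 18.9, 33.4 and 24.5 in the model libraries. The high dose libraries held 30.3, 93.7 and 25.4 FPKM. Every library labelled ApoE-/- lay below every control library. The log2 difference between model and control was -4.67 ± 0.561 (SE), with a limma adjusted p = 0.216.

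The comparison of model with control asked what genotype and high-fat diet together changed in the arch. Macrophage genes were higher in the model libraries. Cd68, a lysosomal protein of macrophages, averaged 176 ± 191 FPKM (SD, n = 3) in model and 12.2 ± 3.94 in control, and Gpnmb, a glycoprotein abundant in lipid-laden macrophages, 487 ± 678 and 5.04 ± 1.61. Model 1 carried these means, at 396 FPKM of Cd68 against 67.5 and 64.2 in model 2 and 3, and 1269 of Gpnmb against 76.6 and 114. Adgre1, which encodes the macrophage surface marker F4/80, averaged 16.0 ± 10.5 and 1.81 ± 0.0805 FPKM, and Cd5l, a secreted macrophage survival factor, 166 ± 185 and 0.387 ± 0.392. The general macrophage list rose (median log2 change 2.46, 15 of 16 members higher, adjusted p = 3.84e-14) and so did the foam cell and lipid-associated macrophage list (median log2 change 1.83, 18 of 20 members higher, adjusted p = 3.04e-10). Both had adjusted p = 0.278 with an estimated correlation, and over the alternatives their adjusted p ran from 1.24e-17 to 0.278 and from 2.08e-14 to 0.278. Over all genes tested 0 members of either list passed, and adjusted over the list alone 13 of 16 and 8 of 20 did. In 14 macrophage and 11 foam cell genes every model library lay above every control library, where chance gives 10% in both directions together. Of all genes tested 16.0% did not overlap in this comparison. Members of these lists are also correlated (estimated at 0.677 and 0.406), so they do not count as independent. The general macrophage list mean was 6.11 ± 0.68 in model and 3.93 ± 0.46 in control, without overlap, and its exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. In only the 5 libraries low in cardiac genes, a setting chosen after seeing the data, the foam cell list had adjusted p = 0.0836.

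Inflammatory, interferon and oxidant genes moved the same way. The inflammatory cytokine, chemokine and adhesion list rose (median log2 change 0.74, 23 of 23 members higher, adjusted p = 9.10e-09), as did the interferon-stimulated list (median log2 change 0.62, 16 of 17 members higher, adjusted p = 2.81e-07) and the NADPH oxidase and other oxidant source list (median log2 change 1.16, 10 of 11 members higher, adjusted p = 2.28e-05). With an estimated correlation these had adjusted p = 0.469, 0.278 and 0.278, the highest over alternatives that began at 5.31e-13, 3.10e-08 and 7.28e-07. Ccl8, a monocyte chemoattractant, averaged 25.1 ± 11.1 FPKM in model and 2.64 ± 0.529 in control, and Selp, the P-selectin of platelets and endothelium, 22.7 ± 16.4 and 2.45 ± 1.45. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, averaged 22.8 ± 12.8 and 3.10 ± 1.68, and the inducible nitric oxide synthase gene Nos2 5.67 ± 0.433 and 2.10 ± 1.02. The interferon response genes Oas1a and Irf7 had log2 differences of 1.40 ± 0.406 and 1.04 ± 0.341 (SE). None passed over all genes tested (0), while 3 inflammatory, 3 oxidant and 0 interferon genes passed when adjusted over the list alone. Of the antigen presentation list only Cd74, Ciita, Cd80 and Cd86 were tested, too few for a list test, and all 4 were higher (median log2 change 1.00). No H2 gene of that list was tested: H2-Aa, a class II chain, stood at 0.126 to 1.14 FPKM where its partner Cd74 stood at 100.2 to 519, and the cause was not tested.

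Lipid and proliferation lists also differed. The lipid efflux and liver X receptor target list rose (median log2 change 0.39, 12 of 16 members higher, adjusted p = 3.06e-04), as did the cell cycle list (median log2 change 0.81, 16 of 18 members higher, adjusted p = 2.84e-07) and the fatty acid and triglyceride synthesis list (median log2 change 0.62, 14 of 16 members higher, adjusted p = 1.39e-04). These lists had, with an estimated correlation, adjusted p = 0.278, 0.469 and 0.651, and over the alternatives adjusted p ran from 1.87e-05 to 0.638, 1.16e-15 to 0.469 and 1.77e-11 to 0.815. Abcg1 and Abca1, cholesterol exporters of macrophages, averaged 31.2 ± 25.2 and 51.2 ± 23.4 FPKM in model against 5.47 ± 1.27 and 15.6 ± 4.93 in control. Mki67, a marker of dividing cells, averaged 5.16 ± 1.12 and 1.41 ± 1.63, and the mitotic cyclin gene Ccnb2 4.40 ± 0.960 and 1.17 ± 0.746. Thrsp, a regulator of lipogenesis, had a log2 difference of 2.65 ± 0.928 and Pnpla3, a lipid droplet protein gene, 2.72 ± 0.830 (SE). The cholesterol synthesis and uptake list fell (median log2 change -0.47, 18 of 23 members lower, adjusted p = 0.0131; adjusted p = 0.777 with an estimated correlation, range over alternatives 2.79e-09 to 0.800), with Hsd17b7 at 0.789 ± 0.241 and 4.08 ± 1.10 FPKM and Msmo1 at 7.76 ± 1.19 and 17.2 ± 8.50. Members that passed when adjusted over the list alone were 7 cell cycle, 2 efflux, 0 fatty acid synthesis and 0 cholesterol genes, against 0 over all genes tested. The cholesterol list had adjusted p = 0.0505 without control 2, 0.378 without control 3 and 0.180 without model 1, 0.800 with array weights and 0.0566 at a mean of at least 5 FPKM. The fatty acid synthesis list had adjusted p = 0.133 without control 2. The cardiac list mean as a covariate, chosen after seeing the data, turned the fatty acid synthesis median to -0.13, and gave the efflux list adjusted p = 0.173, while the 5 libraries low in cardiac genes gave -0.43 for fatty acid synthesis (adjusted p = 0.0508) and adjusted p = 0.638 for efflux.

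Smooth muscle, matrix, blood, nerve and heart lists gave a mixed picture. The modulated smooth muscle and chondrogenic list rose (median log2 change 0.72, 7 of 12 members higher, adjusted p = 0.0200) and so did the fibroblast and collagen list (median log2 change 0.93, 10 of 16 members higher, adjusted p = 0.0212), at adjusted p = 0.706 and adjusted p = 0.777 with an estimated correlation and ranges over alternatives of 1.07e-05 to 0.706 and 2.79e-09 to 0.800. Fn1, the fibronectin gene, averaged 352 ± 169 FPKM in model and 45.6 ± 5.84 in control, Klf4, a factor in the switch of smooth muscle cells, 95.3 ± 24.2 and 49.0 ± 0.592, Postn 263 ± 163 and 108 ± 20.8, and the collagen cross-linking enzyme gene Lox 44.5 ± 30.8 and 14.4 ± 5.36. The modulated list had adjusted p = 0.0505 without control 2, 0.154 without control 3 and 0.248 without model 1, and the fibroblast list 0.0747 without control 2, 0.239 without control 3 and 0.379 without model 1. Array weights gave 0.622 and 0.800, and quantile normalization 0.0654 for fibroblasts. The medians of the modulated and fibroblast lists were 0.13 and 0.41 without model 1, 0.32 and 0.60 without control 3, and 0.88 and 1.18 without control 2. The erythroid list rose (median log2 change 1.49, 8 of 8 members higher, adjusted p = 1.60e-05; adjusted p = 0.469 with an estimated correlation, range 1.67e-08 to 0.469), beside haemoglobin shares of 4.95% to 14.3% in model and 1.99% to 3.69% in control, while Slc4a1, the anion exchanger gene of red cells, averaged 5.12 ± 2.74 and 1.77 ± 0.549 FPKM. The nerve and neuroendocrine list fell (median log2 change -1.91, 14 of 14 members lower, adjusted p = 1.91e-06; adjusted p = 0.469 with an estimated correlation, range 6.66e-10 to 0.469), with Prph, the peripherin gene of peripheral neurons, at 0.435 ± 0.484 and 54.4 ± 54.9 FPKM and the synaptic gene Snap25 at 0.249 ± 0.269 and 45.6 ± 43.7. The cardiac list fell (median log2 change -4.59, 15 of 15 members lower, adjusted p = 6.30e-07; adjusted p = 0.469 with an estimated correlation, range 2.85e-10 to 0.815), although control 3 stood at a list mean of 1.79, below the model libraries. Tnnc1 and Pln averaged 4.72 ± 0.693 and 7.23 ± 3.38 FPKM in model against 599 ± 628 and 254 ± 326 in control. In the 5 libraries low in cardiac genes the cardiac median was 0.50, and with the cardiac covariate 0.039. Neither value tests the cardiac list, since the covariate is that list's own mean and the 5 libraries were picked by it. The covariate also gave the upper end of the cardiac range, 0.815. Members of these lists that passed numbered 0 when adjusted over the list alone and 0 over all genes tested.

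The circadian clock list fell (median log2 change -0.36, 10 of 15 members lower, adjusted p = 0.0106; adjusted p = 0.469 with an estimated correlation, range over alternatives 1.22e-05 to 0.469). Nr1d1, a repressor in the clock loop, averaged 40.9 ± 4.04 FPKM in model and 114 ± 24.0 in control, and Ciart, a clock repressor, 1.66 ± 0.420 and 4.68 ± 1.22. Nr1d1 (chromosome 11, 98767932 to 98775333, minus strand) overlaps the end of Thra on the plus strand, and the labels do not state the strand of the library kit. Adjusted over the list alone, 7 of 15 passed, and over all genes tested 0. The call was lost without control 1 (adjusted p = 0.0589), with the cardiac covariate (0.173) and in the 5 libraries low in cardiac genes (0.279).

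Single genes did not pass. By limma 0 of 12895 genes differed between model and control at an adjusted p under 0.05, with the smallest adjusted p = 0.216 for Apoe, and 821 had an unadjusted p under 0.05 (467 higher, 354 lower, about 645 by chance). Model and control libraries did not overlap in 891 genes that were higher and 1168 that were lower, 16.0% of genes against the 10% that chance gives. Library means overlapped between the groups in 8 of the 15 lists that passed, namely the modulated smooth muscle, fibroblast, cardiac, cholesterol, fatty acid synthesis, NADPH oxidase, cell cycle and clock lists. Ntrk3, a neurotrophin receptor gene, averaged 22.6 ± 5.38 FPKM in model and 4.34 ± 1.13 in control, Nfil3 8.23 ± 1.26 and 2.65 ± 0.605, Blvrb 73.6 ± 13.9 and 30.6 ± 5.36, Dusp8 9.08 ± 0.622 and 3.43 ± 0.743, and the matrix gene Tnc 15.2 ± 8.69 and 2.43 ± 1.05. Among lower genes, Lgals4, a galectin with a near-identical relative in some strains, averaged 16.5 ± 5.06 and 103 ± 51.8 FPKM, Ak1 8.50 ± 1.39 and 39.9 ± 25.5, and Acot1, which shares sequence with Acot2, 5.16 ± 2.19 and 24.8 ± 8.35. With array weights, which ranged from 0.379 for control 3 to 5.92 for model 2, 684 genes passed (261 higher, 423 lower). They held 12 of 15 cardiac genes, all lower, and 7 of 16 general macrophage and 7 of 18 cell cycle genes, all higher. Control 3 was the control library low in cardiac genes, while control 1, with the highest cardiac list mean, 9.78, had a weight of 2.00.

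The other 14 lists did not pass in model against control, with adjusted p from 0.0900 upwards. Their median log2 changes were 0.22 for the T and NK cell list, -0.20 for the B cell list, 0.84 for the neutrophil list, 0.13 for the contractile smooth muscle list, 0.14 for the endothelial list, 0.19 for the white adipocyte list, -0.10 for the brown adipocyte list, 0.035 for the skeletal muscle list, -0.40 for the epithelial and thyroid list, -0.10 for the fatty acid oxidation list, -0.074 for the antioxidant and NRF2 target list, -0.037 for the respiratory chain list, 0.034 for the immediate early list and 0.076 for the heat shock list. Median and mean differed in sign for the contractile, skeletal muscle, antioxidant and immediate early lists, at means of -0.093, -0.24, 0.017 and -0.087. The test took the sign of the mean except for the contractile list. Adjusted over the list alone, 3 heat shock genes passed and 0 in the other 13. Of the genes fixed for every comparison, Trem2, a lipid receptor of macrophages, had a log2 difference of 2.56 ± 1.15, Hmox1, the haem oxygenase gene, 1.18 ± 0.480, Ccl2 1.02 ± 0.620 and Vcam1 1.13 ± 0.953 (SE). The contractile genes Acta2 and Myh11 had 0.33 ± 0.639 and 0.13 ± 0.651, Cpt1a -0.47 ± 0.426, Nqo1 -0.47 ± 0.519 and Sod2 -0.074 ± 0.593. Leaving out model 1 turned Acta2 to -0.057 and Myh11 to -0.32, and Sod2 stood at 0.027 with quantile normalization.

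The comparison of high dose with model asked what gavage with ZCL changed in mice of the same genotype and diet. No gavage was recorded for the model group, so ZCL and the gavage itself cannot be told apart. Macrophage and foam cell genes were lower on average in high dose, through high dose 1 and 2. High dose 3 lay above model 2 and 3 in both lists, with a macrophage list mean of 6.46 against 6.08 and 5.44 and a foam cell list mean of 7.10 against 6.34 and 6.36. Other tissue was present in all 3 high dose libraries. The nerve list mean was 6.32 in high dose 1, and the cardiac list mean 8.24 in high dose 2 and 9.66 in high dose 3. Contractile, fibroblast and endothelial medians fell too, by -0.90, -1.07 and -0.50. Dilution by other tissue was not tested here and cannot be told apart from an effect of treatment. Adgre1 averaged 3.82 ± 2.75 FPKM in high dose and 16.0 ± 10.5 in model, Itgam, an integrin of myeloid cells, 8.23 ± 6.30 and 37.1 ± 36.5, and Cd68 66.0 ± 68.3 and 176 ± 191, with 144 in high dose 3 above 67.5 in model 2 and 64.2 in model 3. The general macrophage list fell (median log2 change -0.99, 16 of 16 members lower, adjusted p = 0.00105) and the foam cell list fell (median log2 change -1.26, 17 of 20 members lower, adjusted p = 0.00171), both at adjusted p = 0.784 with an estimated correlation and with ranges over alternatives of 5.28e-08 to 0.784 and 1.25e-05 to 0.784. Acp5, a phosphatase gene of lipid-laden macrophages, averaged 19.6 ± 7.90 FPKM in high dose and 53.7 ± 8.70 in model, and the scavenger receptor gene Msr1 had a log2 difference of -1.48 ± 0.678 (SE). The NADPH oxidase list fell (median log2 change -0.45, 9 of 11 members lower, adjusted p = 0.0245; adjusted p = 0.784 with an estimated correlation, range 0.00166 to 0.784), with Nox4, an oxidase of vascular cells, at 8.21 ± 6.95 and 32.0 ± 19.5 FPKM and Nos2 at 2.48 ± 0.923 and 5.67 ± 0.433. Members of these lists that passed numbered 0 when adjusted over the list alone and 0 over all genes tested. The macrophage list had adjusted p = 0.252 without high dose 1 (median -0.35) and 0.234 with array weights, and the foam cell list 0.223 without model 1 and 0.0505 without high dose 1 and 0.387 with array weights. The oxidase list had 0.104 without model 1, 0.0547 without model 2, 0.0915 without high dose 1 and 0.0915 without high dose 2, 0.149 with array weights, 0.115 at a mean of at least 5 FPKM, 0.0509 with quantile normalization and 0.159 in the 5 libraries low in cardiac genes.

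Vessel wall lists were also lower on average in high dose, but not in each of its libraries. The contractile smooth muscle list fell (median log2 change -0.90, 13 of 16 members lower, adjusted p = 0.0145), as did the modulated smooth muscle and chondrogenic list (median log2 change -0.71, 8 of 12 members lower, adjusted p = 0.0277), the fibroblast and collagen list (median log2 change -1.07, 12 of 16 members lower, adjusted p = 0.00533) and the endothelial list (median log2 change -0.50, 12 of 14 members lower, adjusted p = 0.00114). The same lists had, with an estimated correlation, adjusted p = 0.797, 0.784, 0.784 and 0.745, and over the alternatives 3.40e-07 to 0.797, 3.77e-05 to 0.784, 1.12e-10 to 0.786 and 3.79e-05 to 0.745. Klf4 averaged 21.0 ± 7.32 FPKM in high dose and 95.3 ± 24.2 in model, Fn1 60.6 ± 71.2 and 352 ± 169, Postn 61.9 ± 55.1 and 263 ± 163, Col6a1 36.5 ± 21.9 and 92.4 ± 34.6, and Itga8, an integrin of smooth muscle, 15.2 ± 10.8 and 96.4 ± 69.2. Smtn, a contractile protein gene, had a log2 difference of -1.18 ± 0.438, Cdh5, the cadherin of endothelial junctions, -1.11 ± 0.376, and Cldn5 -0.67 ± 0.266 (SE). High dose 1 had a contractile list mean of 4.31 and a fibroblast list mean of 3.63, below all other libraries, beside the highest nerve list mean, 6.32. High dose 2 had the highest contractile list mean of the 9 libraries, 7.03. High dose 3 lay above model 2 and 3 in the fibroblast list, at 6.57, and in the modulated list, at 5.79. Over all genes tested 0 members passed. Counts adjusted over the list alone were 3 modulated, 1 contractile, 0 fibroblast and 0 endothelial genes. The contractile list had adjusted p = 0.243 without model 1, 0.641 without high dose 1 and 0.0555 without high dose 3, the modulated list 0.243 without model 1 and 0.641 without high dose 1 with a median of 0.026 without high dose 1, and the fibroblast list 0.133 without model 1 and 0.786 without high dose 1. Array weights gave 0.304, 0.775 and 0.536 for these 3, with the modulated median at 0.31, and the modulated list also had 0.0518 at a mean of at least 5 FPKM, 0.0509 with quantile normalization and 0.0639 with only the 2 groups compared. The contractile, modulated and fibroblast medians were -0.46, -0.18 and -0.56 without model 1, and -0.24, 0.026 and -0.42 without high dose 1.

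Neutrophil, blood and proliferation genes separated the groups in opposite ways. Retnlg, a resistin-like protein of neutrophils, averaged 34.1 ± 15.5 FPKM in high dose and 4.56 ± 2.06 in model, and Ngp, a neutrophil granule protein, 38.6 ± 45.7 and 0.682 ± 0.167. The neutrophil list rose (median log2 change 2.13, 9 of 9 members higher, adjusted p = 9.93e-05), the erythroid list fell (median log2 change -2.59, 8 of 8 members lower, adjusted p = 5.93e-07) and the cell cycle list fell (median log2 change -0.85, 17 of 18 members lower, adjusted p = 3.00e-06). With an estimated correlation they had adjusted p = 0.745, 0.745 and 0.784, the highest over alternatives that began at 1.54e-05, 2.06e-10 and 2.48e-10. Alas2, the haem synthesis enzyme of red cell precursors, averaged 33.0 ± 38.5 and 249 ± 164 FPKM. The mitotic genes Ube2c and Cdk1 averaged 4.16 ± 2.65 and 0.812 ± 0.534 FPKM in high dose against 16.3 ± 5.94 and 2.74 ± 0.414 in model. In 15 of 18 cell cycle genes every high dose library lay below every model library, where chance gives 10% in both directions together. Of all genes tested 22.6% did not overlap in this comparison. The members are also correlated (estimated at 0.683), so they do not count as independent. None passed over all genes tested (0), while 7 of 8 erythroid, 2 of 9 neutrophil and 0 of 18 cell cycle genes passed when adjusted over the list alone. The highest neutrophil list mean, 5.40, was that of high dose 2, the library with the highest airway and skeletal muscle genes.

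Lipid metabolism lists diverged. The cholesterol synthesis and uptake list rose (median log2 change 0.76, 22 of 23 members higher, adjusted p = 9.80e-04) and the fatty acid oxidation and PPAR target list fell (median log2 change -0.94, 19 of 21 members lower, adjusted p = 0.00173), both at adjusted p = 0.784 with an estimated correlation and with ranges over alternatives of 1.12e-10 to 0.784 and 2.39e-06 to 0.863. Msmo1, a sterol oxidase gene, averaged 28.0 ± 18.8 FPKM in high dose and 7.76 ± 1.19 in model. Pdk4, which limits glucose oxidation, averaged 77.5 ± 25.7 and 386 ± 241 FPKM and the receptor gene Ppara 4.31 ± 3.55 and 18.6 ± 10.5. High dose 1 held the highest cholesterol list mean, 4.77, against 3.43 and 2.74 in the other high dose libraries and 2.55 to 3.11 in model. It also held the highest nerve list mean, 6.32, and control 2 was second in both, at 3.82 and 5.32. Without high dose 1 the cholesterol median was 0.18 (adjusted p = 0.322), and array weights gave 0.103. The white adipocyte list fell (median log2 change -0.67, 13 of 15 members lower, adjusted p = 0.0406; adjusted p = 0.875 with an estimated correlation, range 2.77e-04 to 0.893), with Pck1 at 88.7 ± 98.7 and 747 ± 465 FPKM and Aqp7, the glycerol channel gene of adipocytes, at 18.3 ± 12.6 and 45.5 ± 13.7. Adjusted over the list alone, 0 members of these 3 lists passed, and over all genes tested 0. The adipocyte list had adjusted p = 0.0569 without control 2, 0.108 without model 2, 0.460 without model 3, 0.416 without high dose 2 and 0.156 without high dose 3. Its median was -0.35 without model 2, -0.19 without model 3, -0.037 without high dose 2 and -0.51 without high dose 3. It also lost its call with a pseudocount of 0.1 (0.0613), rescaling (0.0529) and quantile normalization (0.0934). With the cardiac covariate its median was 0.36 and that of fatty acid oxidation -0.025 (adjusted p = 0.427 and 0.863), and in the 5 libraries low in cardiac genes 0.50 and -0.15 (0.893 and 0.753).

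Nerve, heart, skeletal muscle and clock lists were higher in high dose taken over its 3 libraries, though the cardiac list was not higher in high dose 1, and the skeletal muscle list passed all model libraries only in high dose 2. The nerve and neuroendocrine list rose (median log2 change 2.64, 14 of 14 members higher, adjusted p = 1.24e-06), as did the cardiac list (median log2 change 4.57, 15 of 15 members higher, adjusted p = 1.41e-04), the skeletal muscle list (median log2 change 2.42, 15 of 15 members higher, adjusted p = 0.00533) and the clock list (median log2 change 0.46, 11 of 15 members higher, adjusted p = 0.00324). These lists had, with an estimated correlation, adjusted p = 0.745, 0.784, 0.784 and 0.745, and over the alternatives 1.78e-12 to 0.745, 1.62e-09 to 0.863, 1.65e-06 to 0.814 and 1.08e-04 to 0.745. Prph averaged 132 ± 171 FPKM in high dose and 0.435 ± 0.484 in model and Snap25 106 ± 141 and 0.249 ± 0.269, with nerve list means of 6.32, 4.97 and 1.92 in high dose 1, 2 and 3. The cardiac list mean of high dose 1 was 1.68, below every model library. The cardiac troponin gene Tnnc1 averaged 523 ± 562 and 4.72 ± 0.693 FPKM, Myl3 334 ± 403 and 1.27 ± 0.470, and the skeletal muscle genes Myl1 and Ckm 244 ± 271 and 519 ± 737 in high dose against 21.7 ± 17.6 and 28.5 ± 39.8 in model. Ciart averaged 9.83 ± 0.712 and 1.66 ± 0.420 FPKM and Nr1d1 116 ± 16.5 and 40.9 ± 4.04. Over all genes tested 0 members passed. Counts adjusted over the list alone were 7 of 15 clock genes and 0 members of the other 3 lists. The skeletal muscle list had adjusted p = 0.0604 without model 1, 0.0801 without model 2 and 0.814 without high dose 2 (median 0.20 without high dose 2). In the 5 libraries low in cardiac genes the cardiac median was -0.70, where high dose 1 alone stood for its group. There the skeletal muscle median was 0.094 and the clock median 0.34. The cardiac covariate gave a cardiac median of 0.032, and the upper end of the cardiac range, 0.863. Neither cardiac median tests the cardiac list, since the covariate is that list's own mean and the 5 libraries were picked by it.

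**Figure D2:**
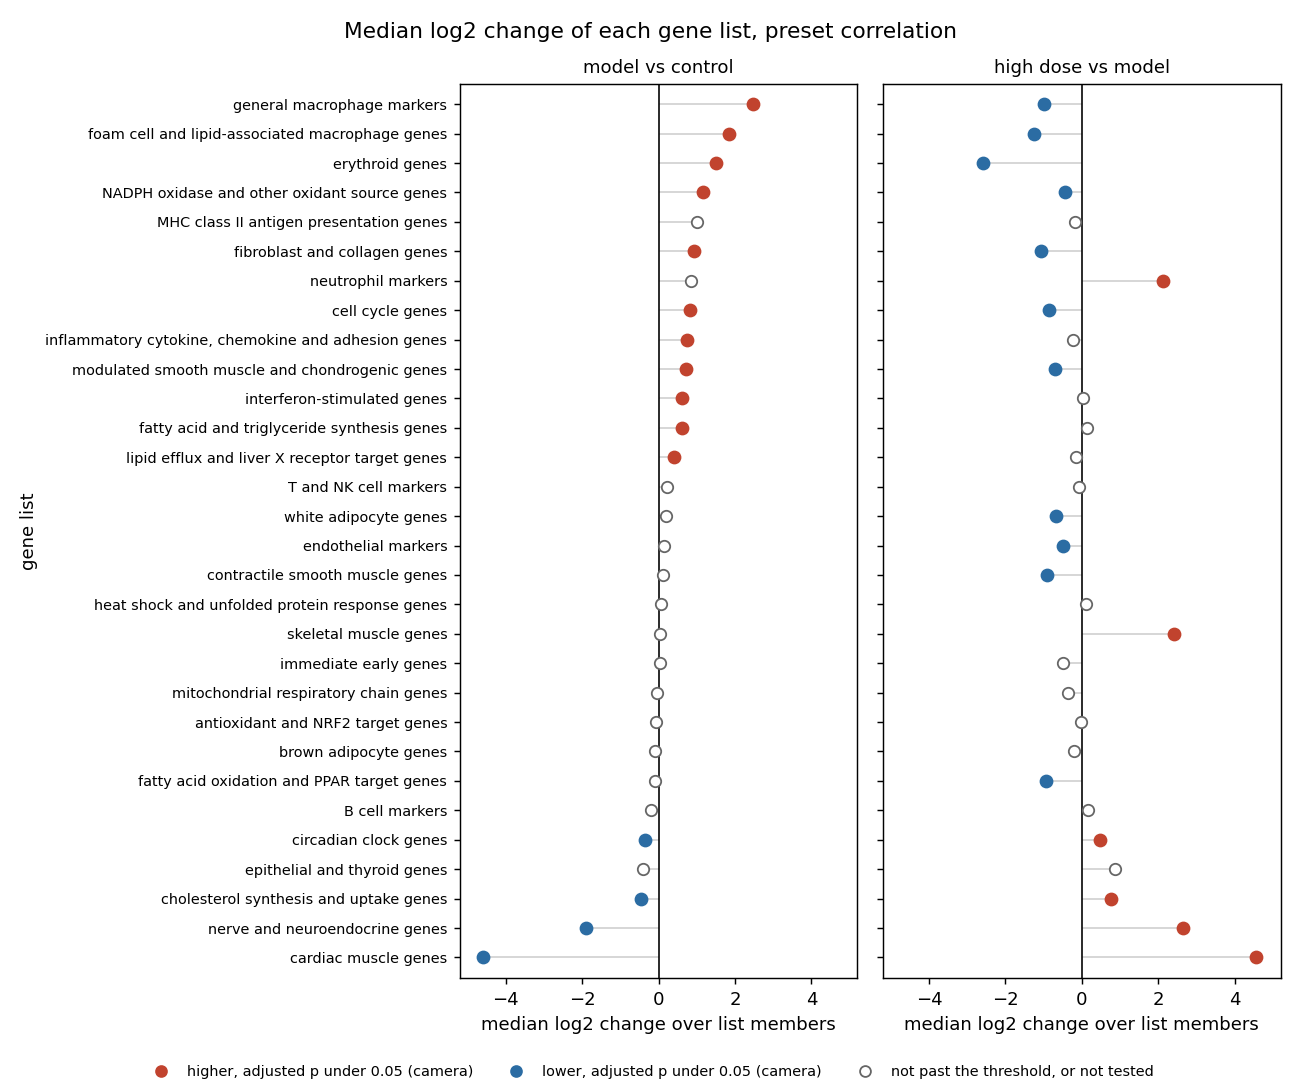
Median log2 change of each gene list in model against control and in high dose against model, on the log2(FPKM + 1) scale. Filled points passed camera at an adjusted p under 0.05, which 15 and 17 of 29 lists did, and the macrophage list lay at 2.46 and -0.99.

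By limma 0 of 12895 genes differed between high dose and model at an adjusted p under 0.05, and 1729 had an unadjusted p under 0.05 (884 higher, 845 lower, about 645 by chance). High dose and model libraries did not overlap in 1504 genes that were higher and 1409 that were lower, 22.6% of genes against 10% by chance. Of the 17 lists that passed, only the neutrophil, nerve, erythroid, cell cycle and clock lists had library means apart between the groups, and 12 overlapped. The smallest adjusted p = 0.0883 was shared by Ntrk3, at 3.12 ± 0.968 FPKM in high dose and 22.6 ± 5.38 in model, and Ciart. Mt1, a metallothionein that binds zinc and copper, averaged 1898 ± 833 and 234 ± 39.3 FPKM, and Ddit4, a stress-induced inhibitor of mTOR signalling, 102 ± 32.6 and 18.7 ± 2.72. Zfp143 had a log2 difference of 1.37 ± 0.184, Tab1 1.28 ± 0.194, Gdf10 -2.08 ± 0.280 and Susd5 -2.26 ± 0.325 (SE). Without high dose 3, 46 genes passed (35 higher, 11 lower), among them Fn1, Klf4 and Ngp, with Htr3a at the smallest p. They also held 2 of 14 nerve genes, Prph and Snap25, both higher, and 3 of 8 erythroid genes, all lower. High dose 3 had the lowest nerve list mean of its group, 1.92, and the highest erythroid list mean, 7.72. Array weights gave 6 genes, Ntrk3, Ciart, Mt1, Cirbp, Dbp and Klf4. Only the 2 groups compared gave 1 (Chrm2), and the 5 libraries low in cardiac genes gave 591 (562 higher), among them 9 of 14 nerve and 9 of 23 cholesterol genes. That setting left 1 control and 1 high dose library, each assumed to vary like the rest.

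The remaining 12 lists did not pass in high dose against model, with adjusted p from 0.182 upwards. Their median log2 changes were -0.062 for the T and NK cell list, 0.17 for the B cell list, -0.21 for the brown adipocyte list, 0.87 for the epithelial and thyroid list, -0.14 for the lipid efflux list, 0.13 for the fatty acid synthesis list, -0.0095 for the antioxidant and NRF2 target list, -0.24 for the inflammatory list, 0.032 for the interferon-stimulated list, -0.35 for the respiratory chain list, -0.49 for the immediate early list and 0.10 for the heat shock list. Median and mean differed in sign for the fatty acid synthesis, antioxidant and interferon-stimulated lists, at means of -0.021, 0.12 and -0.039. The fatty acid synthesis and antioxidant lists tested as higher and the interferon-stimulated list as lower. Adjusted over the list alone, 5 interferon-stimulated, 1 immediate early and 1 heat shock genes passed. Of Cd74, Ciita, Cd80 and Cd86, 3 were lower, and their median change was -0.18. Nqo1, an NRF2 target, had a log2 difference of 1.25 ± 0.519, Hmox1 -0.087 ± 0.480, Sod2 -0.13 ± 0.593, Cybb -1.30 ± 0.623 and Trem2 -1.34 ± 1.15 (SE). Acta2 and Myh11 had -1.38 ± 0.639 and -1.07 ± 0.651, Abca1 -0.42 ± 0.436, Cpt1a 0.12 ± 0.426, Ccl2 0.63 ± 0.620 and Vcam1 -0.63 ± 0.953. Leaving out model 1 turned Hmox1 to 0.43 and Vcam1 to 0.28, and leaving out high dose 1 turned Cpt1a to -0.20.

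Model against control and high dose against model share the model libraries with opposite sign, so that opposite changes arise without any effect. Across genes, which are not independent replicates, the log2 changes correlated at -0.77, against a median of -0.51 in 100 simulated draws of unchanged groups (-0.95 to 0.74). Their covariance was -0.40, against -0.12 simulated (-0.60 to 0.11). Genes with opposite signs made up 74.2%, against 68.9% simulated (26.5% to 89.2%). By limma 0 genes passed in both comparisons. At an unadjusted p under 0.05 in both, 382 genes went opposite ways, against a simulated median of 12 (0 to 1409) and 54.9 for independent lists. In the same direction went 2, against a simulated range of 0 to 34.3 and 55.2 for independent lists. All 5 of these measures lay inside the range of simulated unchanged groups that share the model libraries, so they show no return towards control beyond what sharing gives. The ranges, such as -0.95 to 0.74 for the correlation, are so wide that a real return could also lie inside them. These measures therefore cannot decide whether there was one. The 3 model libraries cannot be split into parts of at least 2. Array weights gave 5 genes called in both with opposite directions, Ciart, Cirbp, Dbp, Klf4 and Ntrk3.

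**Figure D3:**
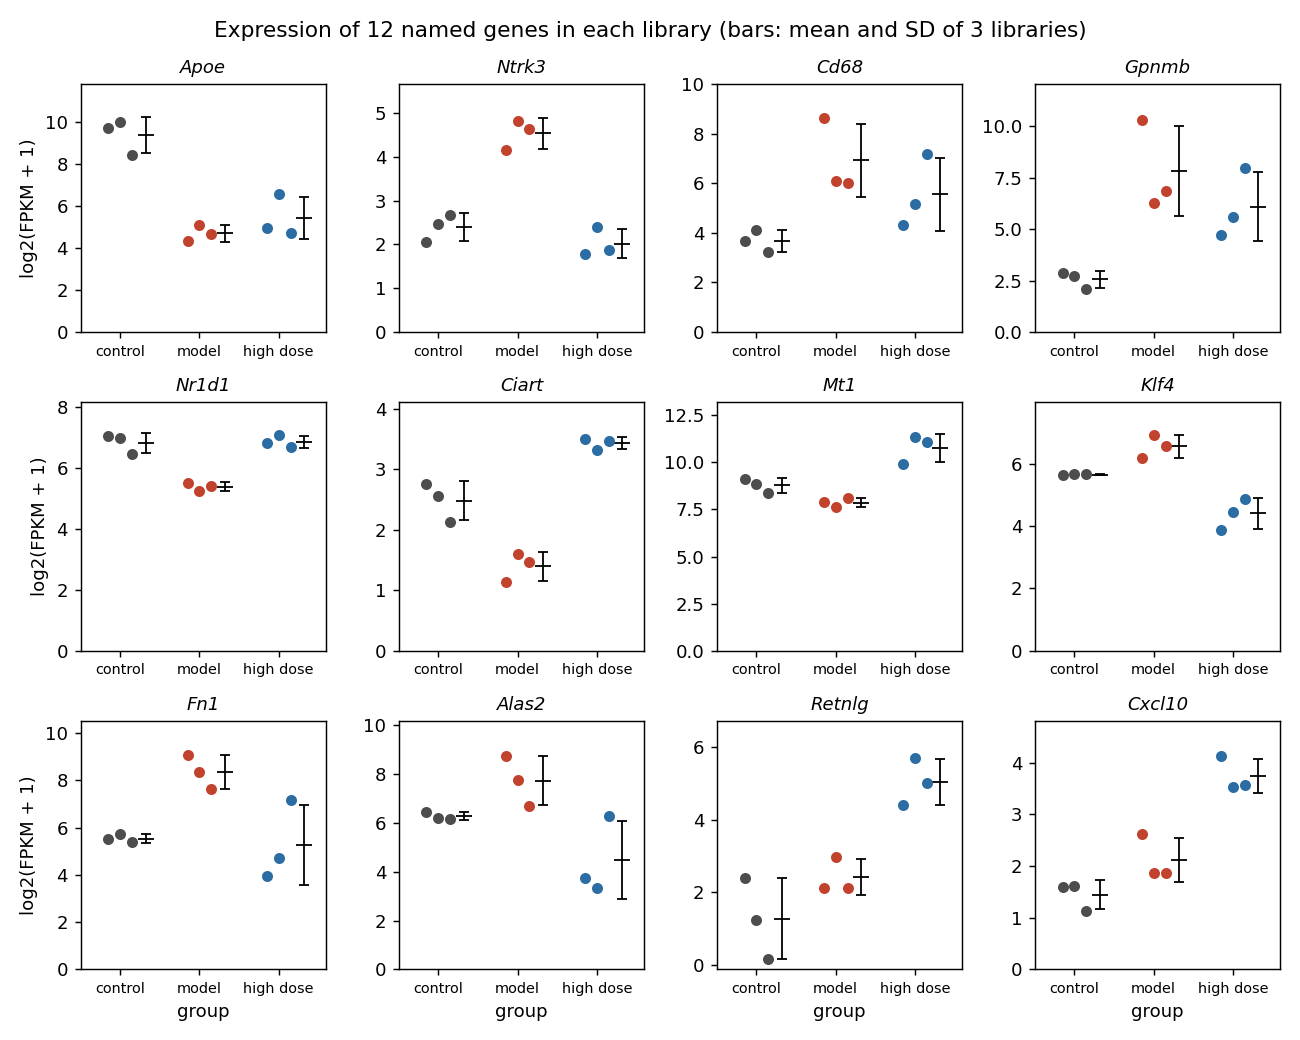
Expression of 12 genes as log2(FPKM + 1) in each library of the control, model and high dose groups, with the mean and SD of 3 libraries. Ntrk3 averages 4.34 ± 1.13, 22.6 ± 5.38 and 3.12 ± 0.968 FPKM in control, model and high dose.

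High dose against control set the treated ApoE-/- arch beside the arch of untreated C57BL/6J mice. Cxcl10, an interferon-induced chemokine, averaged 12.7 ± 3.27 FPKM in high dose and 1.76 ± 0.497 in control, Cxcl2, a neutrophil attractant, 13.4 ± 1.73 and 1.62 ± 2.29, and Retnlg 34.1 ± 15.5 and 1.94 ± 2.14. The neutrophil list rose (median log2 change 2.86, 9 of 9 members higher, adjusted p = 9.42e-10), as did the interferon-stimulated list (median log2 change 0.87, 13 of 17 members higher, adjusted p = 6.01e-06) and the inflammatory list (median log2 change 0.90, 21 of 23 members higher, adjusted p = 4.92e-06). The same lists had, with an estimated correlation, adjusted p = 0.223, 0.577 and 0.577, and over the alternatives 3.63e-11 to 0.223, 6.12e-07 to 0.577 and 7.17e-09 to 0.577. Ctss, a macrophage cathepsin, averaged 258 ± 324 and 26.9 ± 18.1 FPKM and Gpnmb 108 ± 125 and 5.04 ± 1.61. The general macrophage list rose (median log2 change 1.41, 14 of 16 members higher, adjusted p = 9.46e-06) and so did the foam cell list (median log2 change 0.77, 16 of 20 members higher, adjusted p = 0.00212), at adjusted p = 0.577 and adjusted p = 0.622 with an estimated correlation, with ranges of 7.17e-09 to 0.913 and 6.59e-05 to 0.622. None passed over all genes tested (0), while 6 neutrophil, 4 interferon-stimulated, 1 inflammatory and 0 macrophage genes passed when adjusted over the list alone. Without high dose 3 the macrophage, foam cell and inflammatory lists had adjusted p = 0.0914, 0.276 and 0.116, and without control 2 the foam cell list 0.0949. In the 5 libraries low in cardiac genes these 3 lists had 0.913, 0.306 and 0.439, and the camera direction of the first 2 was down, with medians of 0.60 and 0.65.

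Lipid genes differed too. Srebf1, the lipogenic transcription factor gene, averaged 109 ± 29.2 FPKM in high dose and 25.1 ± 14.5 in control, and Acly, which makes cytosolic acetyl-CoA, 133 ± 69.4 and 37.0 ± 12.6. The fatty acid and triglyceride synthesis list rose (median log2 change 0.83, 13 of 16 members higher, adjusted p = 7.45e-05), the lipid efflux and liver X receptor target list rose (median log2 change 0.38, 12 of 16 members higher, adjusted p = 0.00238), and the fatty acid oxidation and PPAR target list fell (median log2 change -0.98, 21 of 21 members lower, adjusted p = 1.60e-06). With an estimated correlation they had adjusted p = 0.622, 0.577 and 0.577, and over the alternatives 2.73e-15 to 0.622, 1.63e-05 to 0.906 and 6.19e-11 to 0.577. Pdk4 averaged 77.5 ± 25.7 and 433 ± 252 FPKM. The respiratory chain list fell (median log2 change -0.37, 24 of 27 members lower, adjusted p = 0.0394; adjusted p = 0.878 with an estimated correlation, range 2.65e-07 to 0.878), with the ATP synthase gene Atp5a1 at 474 ± 209 and 875 ± 442. The brown fat library control 3 had the highest oxidation and respiratory chain list means, 8.08 and 8.94. Members that passed when adjusted over the list alone were 4 fatty acid synthesis, 1 efflux, 0 oxidation and 0 respiratory chain genes, against 0 over all genes tested. Adjusted p for the synthesis list was 0.115 without control 2, for efflux 0.0549 without control 1, for oxidation 0.0640 without control 3 and for the respiratory chain 0.112 without control 1, 0.267 without control 3 and 0.575 without high dose 2, the median of the last being 0.013 without control 3. The respiratory chain call was also lost with a pseudocount of 0.1 (0.0561), rescaling (0.0612), quantile normalization (0.0603) and array weights (0.0957). In the 5 libraries low in cardiac genes the synthesis and efflux lists had 0.560 and 0.906.

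Vessel wall, blood, stress and muscle lists completed the comparison. The contractile list fell (median log2 change -0.69, 12 of 16 members lower, adjusted p = 0.00229), as did the endothelial list (median log2 change -0.30, 14 of 14 members lower, adjusted p = 0.00248) and the erythroid list (median log2 change -1.15, 8 of 8 members lower, adjusted p = 6.27e-04), at adjusted p = 0.622, adjusted p = 0.577 and adjusted p = 0.577 with an estimated correlation and ranges of 6.92e-11 to 0.771, 2.99e-05 to 0.577 and 1.59e-08 to 0.577. Itga8 averaged 15.2 ± 10.8 FPKM in high dose and 52.8 ± 9.78 in control, and Kdr, the vascular endothelial growth factor receptor gene, 16.8 ± 12.1 and 54.6 ± 25.6. The heat shock and unfolded protein response list rose (median log2 change 0.32, 11 of 14 members higher, adjusted p = 0.0224) and so did the skeletal muscle list (median log2 change 2.03, 14 of 15 members higher, adjusted p = 0.00203), at adjusted p = 0.592 and adjusted p = 0.622 with an estimated correlation and ranges of 0.00231 to 0.592 and 1.12e-05 to 0.993. Hspb1, a small heat shock protein gene, averaged 562 ± 306 and 231 ± 72.1 FPKM and Acta1 1280.1 ± 2102 and 35.0 ± 34.7. Adjusted over the list alone, 0 members of these 5 lists passed, and over all genes tested 0. Adjusted p for the contractile list was 0.771 without high dose 1, for the endothelial list 0.0576 without high dose 2, for heat shock 0.0877 without control 2 and 0.218 without high dose 1 and for skeletal muscle 0.163 without control 2 and 0.993 without high dose 2, with a skeletal muscle median of 0.086 without high dose 2. In the 5 libraries low in cardiac genes the skeletal muscle list was called in the opposite direction (median -1.46, adjusted p = 0.00902), with 1 high dose and 1 control library. Quantile normalization gave heat shock 0.0603, and array weights gave endothelial 0.0548 and heat shock 0.103.

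By limma 0 of 12895 genes differed between high dose and control at an adjusted p under 0.05, with the smallest adjusted p = 0.330 for Cxcl10, and 701 had an unadjusted p under 0.05 (340 higher, 361 lower, about 645 by chance). The groups did not overlap in 472 genes that were higher and 647 that were lower, 8.68% of genes against 10% by chance. Of the 14 lists that passed, 3 had library means apart between the groups, the foam cell, neutrophil and interferon-stimulated lists, and 11 overlapped. The 5 libraries low in cardiac genes gave 229 genes, which set high dose 1, rich in nerve genes, against control 3, rich in brown fat genes, with the spread taken from the model libraries, and so cannot be read as a difference between the groups. Cyp26b1, a retinoic acid hydroxylase gene, had a log2 difference of 1.66 ± 0.237, Zfp143 1.06 ± 0.184 and Fosl1 1.59 ± 0.287 (SE). Among lower genes Apoe had -3.94 ± 0.561, Lgals4 -2.59 ± 0.432, Rbbp9 -0.89 ± 0.171, Hyal1 -1.46 ± 0.286 and Zfp866 -0.87 ± 0.173. Of the fixed genes Cd68 had 1.88 ± 0.852, Ccl2 1.65 ± 0.620, Hmox1 1.09 ± 0.480, Abca1 1.18 ± 0.436 and Cybb 1.13 ± 0.623. Trem2 had 1.22 ± 1.15, Acta2 -1.05 ± 0.639, Myh11 -0.94 ± 0.651, Nqo1 0.78 ± 0.519, Vcam1 0.50 ± 0.953, Cpt1a -0.35 ± 0.426 and Sod2 -0.21 ± 0.593. Leaving out control 3 turned Vcam1 to -0.080 and Sod2 to 0.40.

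The other 15 lists did not pass in high dose against control, with adjusted p from 0.0748 upwards. Their median log2 changes were -0.031 for the T and NK cell list, -0.039 for the B cell list, -0.11 for the modulated smooth muscle list, -0.068 for the fibroblast list, -0.46 for the white adipocyte list, -0.10 for the brown adipocyte list, -0.20 for the cardiac list, 0.48 for the nerve list, 0.24 for the epithelial and thyroid list, 0.19 for the cholesterol synthesis list, -0.0035 for the antioxidant and NRF2 target list, 0.75 for the NADPH oxidase list, -0.12 for the cell cycle list, -0.38 for the immediate early list and 0.24 for the clock list. Median and mean differed in sign for the T and NK cell, B cell, epithelial and antioxidant lists, at means of 0.11, 0.07, -0.063 and 0.14, and all 4 tested as higher. Adjusted over the list alone, 1 modulated smooth muscle, 1 immediate early and 1 clock gene passed. Cd74, Ciita, Cd80 and Cd86 were all higher, with a median change of 0.77.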

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

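The cardiac covariate and the 5 libraries low in cardiac genes were chosen after seeing the data; the other settings were planned. Of 964 values of called lists under the alternatives, 817 kept the direction of the camera test and the call, 132 kept the direction only and 15 reversed, and of 2781 values of the named genes reported 2692 kept both, 56 passed the threshold newly and 33 reversed. Robust empirical Bayes leaves the list test as it was, so the calls it kept (15, 17 and 14) repeat the main result. Reversals of the cardiac list followed from the choice of covariate and libraries. By limma 0 genes passed in each comparison under pseudocount 0.1, no filter, the stricter filter and both scalings. Robust empirical Bayes, the replicate block and the cardiac covariate also gave 0. The fold threshold was added to the main fit, which called 0, so it could only give 0 and is no check. Scalings moved the median of all genes by less than 0.1. With an estimated correlation 0 lists passed in each comparison, and the other settings kept 7 lists in model against control, 5 in high dose against model and 3 in high dose against control in every run. Depth limits low genes, and a spread this wide hid simulated changes of 1 on the log2 scale; planned count models were not run because the table holds no counts. The cell cycle list had too few members for a test at a mean of at least 5 FPKM, and the fold threshold gives no list test. The cause of a change was not tested.

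The labels share replicate numbers but do not say what a number stands for. Deviations from group means correlated at -0.52 to 0.31 between libraries of the same number, and 1 library correlated best with its own number. These values gave no sign of pairing. They cannot exclude it, since libraries of a group differed strongly in tissue content. With the replicate block 0 genes passed in each comparison and 15, 17 and 14 lists passed, as without it.

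Array weights gave 684 genes in model against control, 6 in high dose against model, 5 called in both with opposite directions, and 11 lists in high dose against model. The 684 genes held 12 of 15 cardiac genes, all lower. Only the 2 groups compared gave 1 gene in high dose against model. The 5 libraries low in cardiac genes gave 591 genes in high dose against model and 229 in high dose against control. Left-out libraries gave 0 to 46 genes in high dose against model and 0 in the other comparisons and for opposite directions, and 14 to 19, 10 to 17 and 14 to 17 lists.

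Some log2 differences changed sign. In model against control, quantile normalization gave Sod2 0.027 and array weights gave Myh11 -0.11, Sod2 0.47 and Vcam1 -0.058. In high dose against model, array weights gave Hmox1 0.39 and Vcam1 0.49. The cardiac covariate gave Nqo1 0.14, the cardiac list 0.039 and fatty acid synthesis -0.13 in model against control, and Sod2 0.48, white adipocytes 0.36 and the cardiac list 0.032 in high dose against model. The 5 libraries low in cardiac genes gave Cpt1a 0.34, Nqo1 0.10, the cardiac list 0.50 and fatty acid synthesis -0.43 in model against control. They gave Tnnc1 -0.21, Sod2 0.19, white adipocytes 0.50 and the cardiac list -0.70 in high dose against model. In high dose against control they gave Acta1 -0.91, Cpt1a 1.10 and skeletal muscle -1.46. The values of the cardiac list under the covariate and in the 5 libraries follow from how these were chosen, and do not test that list. The median stayed above 0 and only the direction of the test turned for skeletal muscle in high dose against model, at 0.094, and for macrophages 0.60, foam cells 0.65 and fatty acid synthesis 0.22 in high dose against control. The reverse held for modulated smooth muscle in high dose against model, whose median was 0.31 with array weights and 0.026 without high dose 1, and for the clock list in model against control, at 0.024 in the 5 libraries, where the median turned and the test did not.

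Leaving out 1 library at a time gave, in model against control, Acta2 -0.057 to 0.61, Myh11 -0.32 to 0.40 and Sod2 -0.58 to 0.53. In high dose against model it gave Abca1 -0.68 to 0.0038, Cpt1a -0.20 to 0.38, Hmox1 -0.49 to 0.43, Sod2 -0.60 to 0.16, Ccl2 -0.011 to 1.16 and Vcam1 -1.49 to 0.28. In high dose against control it gave Sod2 -0.71 to 0.40, Vcam1 -0.37 to 0.94, the respiratory chain -0.80 to 0.013 and skeletal muscle 0.086 to 2.99, the last turning only in the direction of the test.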

Other observations

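All the tests of explanations in this part were chosen only after the results were seen. So were the genes named here, except those that the rule for named genes had already selected, such as Mt1, Lgals4 and Blvrb. Mt1, Mt2 and Mt3, which encode metallothioneins, were each higher in every high dose library than in every model library, and none passed by limma. Mt2 stood at 478, 2520.4 and 1486 FPKM in high dose 1, 2 and 3 and at 181, 72.9 and 152 in the model libraries, and Mt1 at 968, 2574 and 2151 against 235, 195 and 273. In control Mt2 lay at 147 to 250.1 FPKM. Mt3, a metallothionein first known from brain, stood at 53.9, 114 and 12.3 FPKM in high dose and at 0.264 to 0.495 in model. With array weights Mt3 was also among the genes called in model against control. Mt1 there had a log2 difference of -1.18 (limma adjusted p = 0.0531). For Mt1 and Mt3 a difference from model alone does not show a rise above control. Cirbp, a cold-inducible RNA-binding protein gene, stood at 66.8 to 88.0 FPKM in high dose, 22.0 to 29.1 in model and 38.8 to 69.6 in control, and Dbp, a clock output gene, averaged 68.4 ± 17.4, 10.4 ± 7.55 and 43.3 ± 13.8 in the same order. Adjusted p in high dose against model by limma was 0.141 for Mt1, 0.162 for Mt2, and 0.159 for Cirbp, Mt3 and Dbp.

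Lymphocyte genes varied inside every group. Cd79a, a subunit of the B cell receptor, stood at 66.4 FPKM in control 2, 43.6 in high dose 1 and 35.7 in model 2, and at 3.31, 3.35 and 2.10 in the lowest library of each group. The T cell gene Cd3e reached 13.6 FPKM in control 2 and 5.29 in high dose 1 and lay between 0.152 and 1.81 elsewhere. The lung surfactant gene Sftpc stood at 1599 FPKM in control 2 and at most at 11.2 in any other library.

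Macrophage genes were higher in model than in control. If heart muscle in control libraries had diluted all other cells, endothelial and contractile genes would have risen alike, but the macrophage median exceeded the larger of theirs by 2.32 log2 (1.53 to 2.76, 95% bootstrap over genes, which leaves out the spread between libraries). Lymphoid tissue in the model arches would have raised T and B cell genes, and the macrophage median exceeded the larger of theirs by 2.24 (1.13 to 2.92). Control 2 had the highest T and B cell list means of the 9 libraries, 3.49 and 4.33, which lowers both medians. T cell list means were 1.69 to 2.37 in model, against 0.995 in control 1 and 0.538 in control 3. B cell list means were 1.28 to 3.34, against 1.45 and 1.26. The second difference therefore cannot decide about lymphoid tissue. The first argues against dilution by heart muscle as the whole cause. It does so only if heart muscle brought few endothelial or contractile genes of its own, which was not tested. Control 3, low in cardiac genes, had the lowest macrophage list mean of the 9 libraries, 3.47. It also had the highest brown adipocyte list mean, 8.12, and dilution by fat was not tested. A hypothesis is that macrophages accumulated in the arch of ApoE-/- mice on a high-fat diet, which cell counts or CD68 staining of arch sections would decide. Other sources of the rise, blood among them, were not tested. Erythroid and macrophage list means were highest in model 1, at 9.66 and 6.81, and lowest of its group in model 3, at 7.97 and 5.44. High dose 3 led its group in both, at 7.72 and 6.46, but control 1 had 7.68 and 3.94.

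A clock index, the mean of 10 clock genes minus that of Arntl, Clock, Npas2 and Cry1, was lower in every model library than in every high dose library, while 7 of the 15 genes of the clock list separated the groups singly. A mixture of tissues would vary within groups, but the gap in the index between the nearest model and high dose libraries was 0.960 log2, against a widest range within either group of 0.363; in control the index ran from 1.54 to 2.17. Different hours of collection would part these 4 genes from the other 10, and the difference of the medians was -0.97 (exact p = 0.0779 over permutations of genes, which are not independent, adjusted p = 0.117 over 3 comparisons). In model against control it was 1.10 (exact permutation p = 0.0300, adjusted p = 0.0899). Hour of collection and treatment cannot be told apart for these genes, since no label gives the hour.

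Genes near Apoe could carry DNA of the donor strain in which Apoe was disrupted. Within 10 Mb of Apoe, 3 of 196 tested genes (1.53%), Lgals4, Blvrb and Plaur, had an unadjusted p under 0.01 for both ApoE-/- groups against control, against 85 of 12301 elsewhere (0.691%; one-sided Fisher exact p = 0.160). Lgals4 and Blvrb ranked 2 and 4 of all genes, and as many such genes lay in 7 of 143 windows of the same size. Donor DNA and the genotype or diet itself cannot be told apart from these values, because every ApoE-/- library would carry both.

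The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Counts of called genes cannot be tested so: each real split called 0 by limma, so all 10 splits called as many whatever they held, with 10, 0 and 1 at the highest other in model against control, high dose against model and high dose against control. At an unadjusted p under 0.05 model and control gave 821 genes and the highest other split, control 1, control 2 and model 1 against the rest, gave 1653, with 2 splits as large. High dose and model gave 1729 against 1236 at the highest other, and 1 split was as large. High dose and control gave 701 against 1423 at the highest other, and 8 splits were as large.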
